A study of Arabidopsis thaliana with 8 samples.

How the data were processed

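RNA of 8 Arabidopsis thaliana samples of ecotype Columbia 0 was measured on 1-channel arrays: 4 samples of the wild type (WT) and 4 of the psah2k double mutant, numbered 1 to 4 within each genotype. Groups and numbers were taken from the sample titles, per the labels. The organ, the growth conditions and whether the samples of a genotype came from separate plants are not given in the sources used here, so p-values measure the spread between these samples, which may be technical. The deposited table holds 1 intensity for each of 3439 features on each array, on a linear scale from 0 to a ceiling of 100. How the authors subtracted background, scaled the arrays or set the value of 100 is not given in the sources used here, so it is unknown whether the arrays were already scaled to each other. The median intensities were 0.333, 0.336, 0.304 and 0.305 on WT arrays 1 to 4 and 0.0527, 0.0506, 0.0560 and 0.0582 on psah2k arrays 1 to 4. The number of arrays limits the precision.

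Features were named through GEO's platform annotation of the array, which lists 1562 of them. Of these, 692 had 1 gene and 870 had several genes. The other 1877 features are unnamed here. For features with 1 gene, 690 names were brought up to date through the gene identifiers of the TAIR10.1 RefSeq table, and 2 did not match it. No gene was named from a feature with several genes, and no coordinates were used.

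Intensities were log2 transformed, with values of 0 treated as missing. The array medians of the log2 values spanned 2.14, more than the 0.1 that had been set as the limit for leaving the values as deposited, so the arrays were quantile normalized. The 2353 features with at least 3 values in each genotype were tested for psah2k minus WT with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes below refer to the normalized values, and intensities given as mean ± SD are the deposited ones. After quantile normalization the median log2 fold change of all tested features was −0.12. It was −1.77 for the values as deposited, 0.18 after centring each array on its median and −0.53 after centring on its upper quartile. Since most signals shifted with the scaling, each named gene was checked under all 4 scalings. Median and upper quartile centring change the deposited log2 values only by a constant per array, so the 4 scalings are not independent checks.

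The 18 gene lists of chloroplast functions, holding 302 entries, were fixed before the data were examined, as were the tests, the main alternatives and the rule for naming genes. The rule took the genes targeted in the mutant with their paralogs. It also took the 12 largest rises and the 12 largest falls among features with 1 gene that passed the threshold and had every psah2k array on one side of every WT array. Values of 0 were left out of this condition. The rises of AT2G39000, AT4G24160 and AT4G17260 met it although a psah2k array was at 0, below all WT arrays. From each list the rule took up to 4 members with the smallest p. Lists with at least 3 tested members were compared with the other features by limma's camera with a preset inter-gene correlation of 0.01, with an estimated correlation and limma's fry beside it. Arrays were compared by exact permutation tests, two-sided, and by Spearman's rho over the 1806 features above 0 on all 8 arrays.

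The limma step was tested on simulated data with 200 of the 2353 features changed, rises and falls in equal number. Values were simulated on the normalized scale without a shift of the whole distribution. Normalization, and false calls that it may cause, were therefore not covered. The limma step recovered 49% of the changes of 1 log2 unit and 77% of those of 2 log2 units. Of its calls, 8.70% were false, more than the 5% aimed at. With arrays simulated as correlated within numbers 1-2 and 3-4, at 0.313 as estimated from the data, 10.6% of the calls were false. In the data 1246 features were called, many more than the 200 changed in the simulation. Recovery and the false share depend on how many features change, so these rates need not hold for the real fit. Alternatives covered the scaling, filters on dim features and on values of 0, a pseudocount of 0.0309, the variance model, array weights, the replicate number as a block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.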

Results

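Transcripts of the psah2k line, an Arabidopsis double mutant in subunits of photosystem I, were compared with those of WT on 4 arrays per genotype. Photosystem I is the thylakoid complex that passes electrons from plastocyanin to ferredoxin. The labels describe a comparison of a mutant lacking 2 of its proteins with WT, but they name the proteins in different ways: the line name points to subunits H and K, and the description to E1 and K. No feature of the array was assigned to PSAE1, PSAH2 or PSAK alone, nor to the paralogs PSAE2 and PSAH1, so the genotype could not be checked from the targeted transcripts here.

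The genotypes differed in the whole distribution of intensities. The median deposited intensity of an array was 0.320 ± 0.0176 (SD, n = 4) in WT and 0.0544 ± 0.00338 (SD, n = 4) in psah2k. The exact permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. The upper quartile was 0.627 ± 0.0360 in WT against 0.188 ± 0.00634 in psah2k, while the 99th percentile was 9.92 ± 1.03 against 14.1 ± 2.05. Between 448 and 472 features were listed at 0 on the WT arrays and between 739 and 1014 on the psah2k arrays. Among the 236 brightest tested features the median deposited log2 ratio of psah2k over WT was 0.20, and among the others it was −1.96. Spearman's rho across features was 0.960 to 0.987 between WT arrays, 0.853 to 0.897 between psah2k arrays and 0.606 to 0.670 between the genotypes. Features are not independent replicates.

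**Figure D1:**
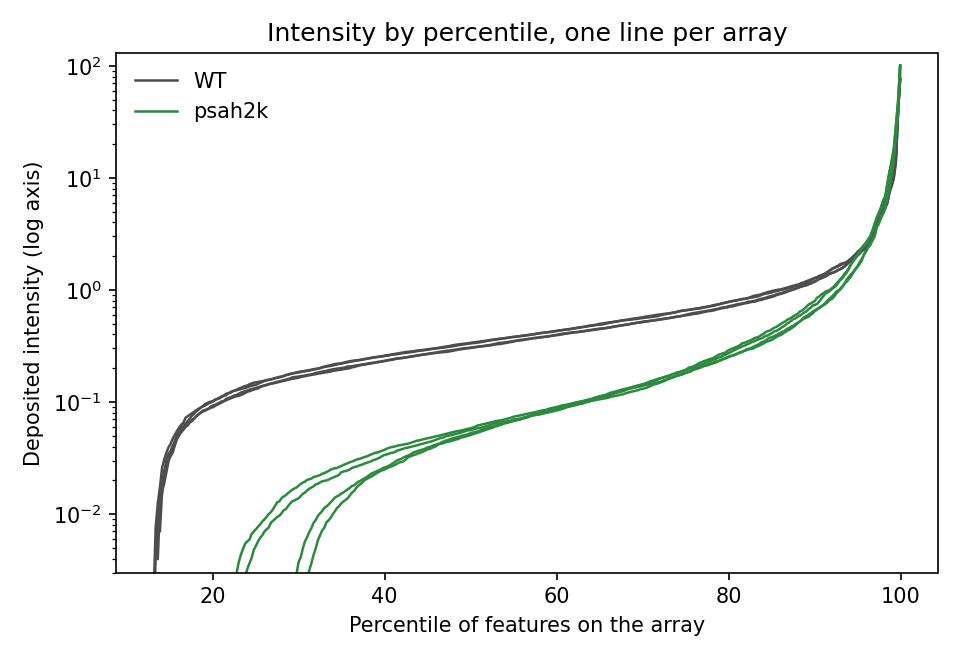
Deposited intensity on a log axis against the percentile of features on the array, with 1 line for each of the 4 WT (grey) and 4 psah2k (green) arrays. The psah2k lines lie below the WT lines over most of the range, with medians near 0.0544 against 0.320. They cross above them among the brightest features, with 99th percentiles near 14.1 against 9.92.

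Against this background, a set of transcripts with middling to high intensity on the WT arrays was far dimmer on the psah2k arrays. AT3G52070 fell from an intensity of 3.25 ± 0.207 to 0.0514 ± 0.0373 (SD, n = 4 each), a log2 fold change of −5.42 (SE 0.673, limma adjusted p = 0.000419), which was −4.53 without psah2k 2. AT5G52810, which encodes SARD4 of pipecolate synthesis, fell from 1.79 ± 0.102 to 0.0497 ± 0.0292 (log2 −4.17). AT1G01080, an RNA-binding protein gene, fell by 3.46 on the log2 scale, and AT2G32040, a gene for a plastid folate transporter, by 3.39 (−2.45 without psah2k 4). The gene AT4G38670 for a thaumatin-like protein, a family that includes defence proteins, fell by 3.32.

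The other 7 of the 12 largest falls were AT3G03890 (−4.46), AT1G07970 (−4.43), AT3G17550 (−4.12), AT1G73120 (−4.01), AT1G16080 (−4.01), AT4G35660 (−3.97) and AT5G17840 (−3.34) on the log2 scale. Of the 12, 11 passed the test under all 4 scalings. With values of 0 set to the smallest positive value of the array, AT4G35660, AT1G01080, AT2G32040 and AT5G17840 missed it (adjusted p = 0.108, 0.0742, 0.0723 and 0.0530), with log2 fold changes of −5.13, −5.26, −3.30 and −2.90. AT5G17840 also missed it after median centring (adjusted p = 0.0548) and whenever any single WT array was left out (adjusted p up to 0.0638), and its log2 fold change was −2.19 without psah2k 2. All 12 had WT intensities between 0.504 and 4.41, above the median of 0.437 over tested features. Their psah2k means were only 0.00888 to 0.185. AT3G03890, AT4G35660, AT1G01080 and AT4G38670 each had a psah2k array at 0. The sizes of these falls thus rest on low psah2k values. For psah2k arrays, with a mean median of 0.0544 and a mean upper quartile of 0.188, not all were dim. AT1G73120 (0.185) and AT1G16080 (0.159) were near that upper quartile.

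The largest rises were of genes with dim signals on the WT arrays. AT2G39000, a gene of the GNAT family of acetyltransferases, had the highest log2 fold change, 5.06 (SE 0.899, limma adjusted p = 0.00349). Its deposited intensities were only 0.0291 ± 0.0185 in WT and 0.0790 ± 0.0726 in psah2k, with 1 psah2k array at 0. With values of 0 set to the smallest positive value of the array it missed the threshold (log2 6.28, adjusted p = 0.0530). It also missed it with only numbers 3 and 4 (log2 4.88, adjusted p = 0.0783). Its log2 fold change depended on the processing: it was 1.98 as deposited, 1.84 with a pseudocount, 3.25 after upper quartile and 3.94 after median centring, and 4.45 without WT 3 to 5.69 without WT 4. AT4G02580, which encodes a subunit of mitochondrial complex I, rose from 0.125 ± 0.0414 to 0.289 ± 0.0958 (log2 3.26, and much less as deposited, as these means show). AT4G38490 rose from 0.207 ± 0.0487 to 0.580 ± 0.199 (log2 3.08, and 1.45 as deposited), and the aldo-keto reductase gene AT1G04420 from 0.153 ± 0.00931 to 0.263 ± 0.0162 (2.76 and 0.79). AT2G04700, which encodes the catalytic subunit of ferredoxin-thioredoxin reductase, rose from 0.168 ± 0.00928 to 0.244 ± 0.0107 (2.52 and 0.54). These 5 passed the test under all 4 scalings.

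The other 7 of the 12 largest rises did not pass it on the deposited scale. They were TPP2 for tripeptidyl peptidase II (log2 3.12, and 0.32 as deposited), AT1G51080 (2.62 and 0.33), the lysophosphatidic acid acyltransferase gene AT4G24160 (2.57 and 0.24), AT3G27110 (2.44 and 0.15), AT1G06510 (2.29 and 0.08), AT3G06870 (2.24 and 0.17) and the lactate dehydrogenase gene AT4G17260. AT4G17260 turned direction, from a log2 fold change of 2.56 after quantile normalization to −0.46 as deposited. Among the 4 scalings AT4G24160 passed after quantile normalization alone, and it missed the threshold with numbers 1-2 and 3-4 averaged first (adjusted p = 0.0824). Its deposited mean in psah2k rests on psah2k 2 at 0.565, the other psah2k arrays being at 0, 0.0570 and 0.0523 against 0.0647 to 0.133 in WT. With only numbers 3 and 4 its log2 fold change was 1.35, and without psah2k 2 too few values were left to test it. AT4G17260 and AT3G27110 missed the threshold after upper quartile centring, and AT3G27110 also with only numbers 1 and 2 (adjusted p = 0.102). The deposited mean of AT3G27110 in psah2k rests on psah2k 1 at 0.497, the others being at 0.0629, 0.0869 and 0.0995 against 0.0932 to 0.127 in WT. On the deposited scale the arrays of the genotypes overlapped for each of these 7 genes. WT intensities of the 12 lay between 0.0291 and 0.207.

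Among nuclear genes of the photosynthetic apparatus, several bright signals were higher in psah2k. Bright features as a class also stood higher there, with a median deposited log2 ratio of 0.20 in the brightest 236 against −1.96 in the others. These values alone therefore do not show a rise in transcript amount. A comparison with features of like brightness, given at the end, did not decide it. PSAN, a lumenal subunit of photosystem I that helps plastocyanin to dock, rose from 4.36 ± 0.884 to 11.9 ± 1.55 (log2 1.02, limma adjusted p = 0.00490) and was the 1 measured member of the 12 in the photosystem I list. Of the 3 tested of the 14 listed photosystem II subunits, PSBY rose from 1.92 ± 0.128 to 3.86 ± 0.942 (log2 0.83). PRK, the Calvin cycle enzyme that makes ribulose bisphosphate, rose from 1.58 ± 0.168 to 3.40 ± 0.413 (log2 1.11 as deposited). AT1G74470, listed as CHLP, the geranylgeranyl reductase of chlorophyll synthesis, rose from 2.83 ± 0.199 to 4.86 ± 0.913 (log2 0.48). PSAN, PSBY, PRK and AT1G74470 passed under all 4 scalings. Median and upper quartile centring add little as checks here, since they raise the deposited log2 fold changes. That of PSAN was 1.47 as deposited and 3.40 and 2.70 after them. PSAN, PSBY, PRK and AT1G74470 missed the threshold once numbers 1-2 and 3-4 of each genotype were averaged first (adjusted p = 0.0832, 0.0556, 0.0676 and 0.144).

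Other members of these lists depended on the scaling. PSBW, a small photosystem II subunit, was at 45.2 ± 0.904 in WT and 40.4 ± 4.80 in psah2k. Its log2 fold change was −0.60 (adjusted p = 0.0298) after quantile normalization, −0.17 as deposited, and in the other direction, 1.77 and 1.06, after median and upper quartile centring. PSBW also lost its call without any one of 7 of the 8 arrays, psah2k 4 being the exception (adjusted p up to 0.0852). PSB27, a photosystem II assembly factor, had a log2 fold change of −0.36 (adjusted p = 0.554), which was 1.21 and past the threshold after median centring, 0.51 after upper quartile centring and −0.91 (adjusted p = 0.0163) without WT 4. LHB1B2, the light-harvesting gene listed as LHCB1.5, had intensities of 10.8 ± 2.14 and 19.3 ± 1.25. It had a log2 fold change of 0.01 (adjusted p = 0.961) after quantile normalization, yet was called higher under the other 3 scalings. CHLM, the Mg-protoporphyrin methyltransferase gene, had 0.17 (adjusted p = 0.516), and −1.72 as deposited, where it passed.

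**Figure D2:**
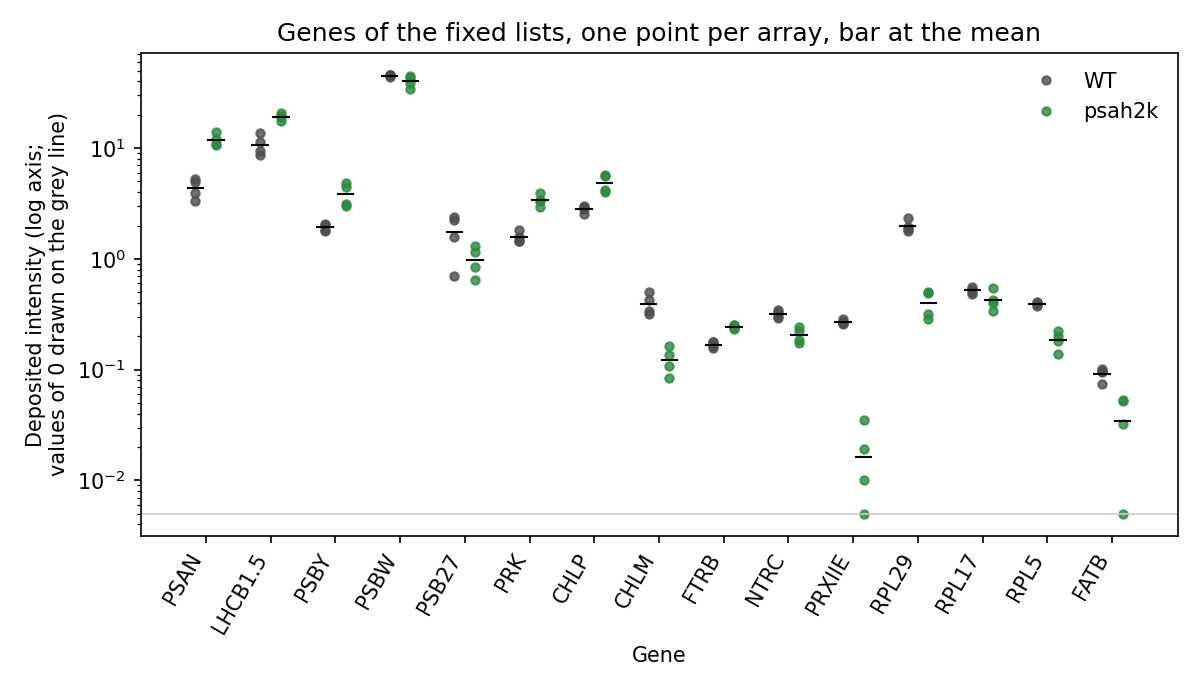
Deposited intensity on a log axis of the 15 tested genes of the fixed lists, with 1 point for each of the 4 WT (grey) and 4 psah2k (green) arrays and a bar at each group's mean. PSAN, PSBY, PRK and CHLP are higher and PRXIIE lower in psah2k under all 4 scalings, while PSBW turns direction with the scaling.

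The plastid antioxidant and thiol redox genes moved both ways. Of the 3 tested of 28 listed, AT2G04700 rose, as given above. NTRC, the NADPH-dependent thioredoxin reductase of plastids, rose after quantile normalization (log2 1.15), but its log2 fold change was −0.65 as deposited, from 0.319 ± 0.0246 to 0.205 ± 0.0322, and passed there as lower (adjusted p = 0.00643). AT3G52960, listed as PRXIIE, a plastid peroxiredoxin gene, fell from 0.270 ± 0.0108 to 0.0162 ± 0.0150 (log2 −1.40, adjusted p = 0.0157), and did so under all 4 scalings, but its adjusted p was 0.135 with numbers 1-2 and 3-4 averaged first and 0.302 with values of 0 set to the smallest positive value.

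Of the 3 tested of 36 plastid ribosomal protein genes, AT5G65220 (RPL29) fell from 1.97 ± 0.243 to 0.399 ± 0.113 (log2 −1.84), though after median centring its −0.41 missed the threshold. AT3G54210 (RPL17) and AT4G01310 (RPL5) rose after quantile normalization (log2 1.04 and 0.65), but were at −0.30 and −1.09 as deposited, where AT4G01310 passed as lower (adjusted p = 0.000757). FATB, the plastid acyl-ACP thioesterase gene of fatty acid synthesis, had log2 1.63 and, as deposited, −1.04, both past the threshold. In all, 9 of the 15 tested list members rose and 3 fell after quantile normalization, and 5 rose and 1 fell under all 4 scalings. With numbers 1-2 and 3-4 averaged first, 5 of the 15 passed, and of the 6 called under all scalings AT2G04700 alone did. Adjusted over the list alone, 12 of the 15 passed, as over all features. The other 10 lists, among them photosystem I antenna, photorespiration, starch metabolism and the marker list of roots and non-green plastids, had no tested member.

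No list as a whole passed the camera test. The adjusted p was 0.869 for photosystem II subunits (median log2 −0.36), 0.471 for the redox list (1.15) and 0.869 for ribosomal proteins (0.65). The medians changed sign with the scaling, but so did the median of all tested features. That was −0.12 after quantile normalization, −1.77 as deposited, 0.18 after median and −0.53 after upper quartile centring. The redox and ribosomal medians lay above it under each scaling. The photosystem II median lay below it after quantile normalization and above it under the other scalings. That of photosystem II subunits was 1.77 after median and 1.06 after upper quartile centring (adjusted p = 0.111 and 0.0502), and as deposited the redox list was at −0.65 and the ribosomal list at −1.09. With an estimated correlation, adjusted p = 0.866, 0.838 and 0.866 after quantile normalization, so 0 lists passed. With features of 1 gene, 0 lists had an unadjusted camera p under 0.05 after quantile normalization, the smallest being 0.157. Under each of the other scalings the photosystem II list was under 0.05 before adjustment in camera. It missed the threshold after adjustment there, with an adjusted p of 0.0939 as deposited. Features shared by several genes of a list were then added, an alternative chosen after seeing the data. After quantile normalization the redox list alone was under 0.05 before adjustment. The adjusted p was 0.127 for its 5 features and 0.129 for the 3 of chlorophyll synthesis, so again 0 lists passed. The fry test, which does not compare a list with other genes, called 1 list, the redox genes, as higher (adjusted p = 4.31e-05). For photosystem II subunits the median was below 0 while camera's direction was up. For ribosomal proteins the mean of −0.05 and fry's direction were opposite to the median. Each list had only 3 tested members with 1 gene.

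Over the array, limma called 1246 of the 2353 tested features (53.0%), 620 higher and 626 lower in psah2k. Of these, 242 had 1 gene, 97 higher and 145 lower, and 867 of the calls were over 2-fold. With missing values left out, every psah2k array lay on one side of every WT array for 54.6% of tested features after quantile normalization. Chance gives 2.86% if the 4 arrays of a genotype are independent and all have values, and more where a value is missing. It gives 33.3% if numbers 1-2 and 3-4 each count as 1 sample. Only 1806 of the 2353 tested features had values on all arrays. The balance of directions followed the scaling: as deposited, 172 were higher and 1718 lower. After median centring there were 817 higher and 396 lower, and after upper quartile centring 567 and 790. Called in the same direction under all 4 scalings were 140 features as higher, 24 of them with 1 gene, and 368 as lower, 94 of them with 1 gene. Of the 620 higher after quantile normalization, 220 were called lower as deposited.

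**Figure D3:**
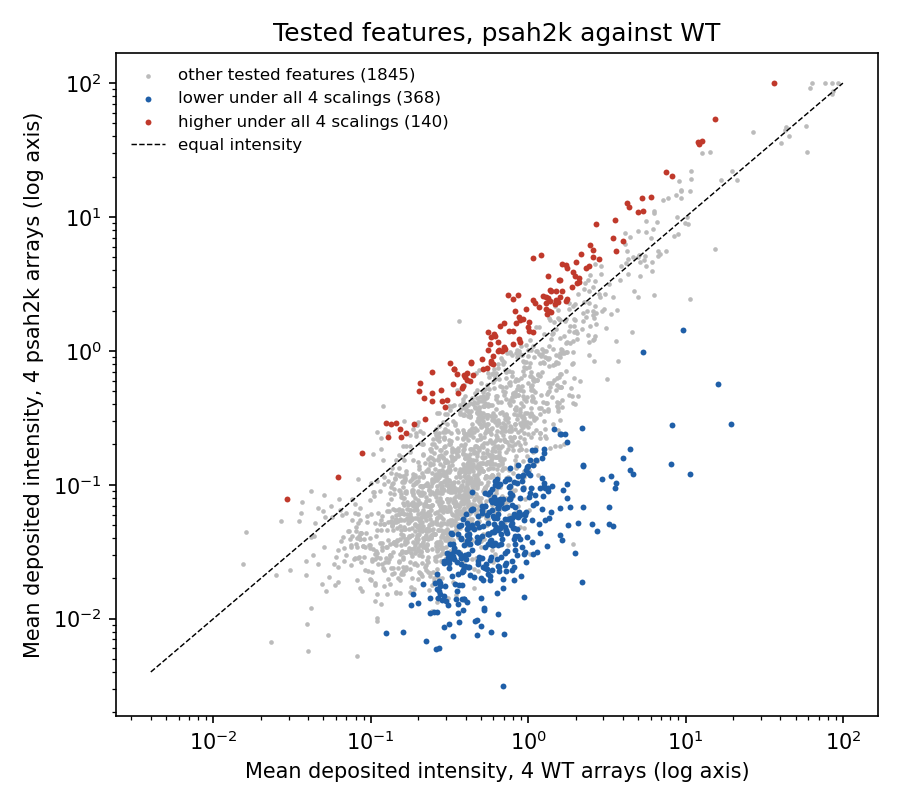
Mean deposited intensity of the 4 psah2k arrays against that of the 4 WT arrays for the 2353 tested features, both on log axes, with a dashed line at equal intensity. The 140 features higher (red) and 368 lower (blue) under all 4 scalings lie on both sides of the main cloud, which itself bends below the line at low intensity.

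Some of the brightest differences were of features without a gene name here, chosen after their values were seen. Feature 3099 fell from 19.4 ± 3.10 to 0.287 ± 0.0987 (log2 −5.99, limma adjusted p = 6.52e-07), and feature 513 from 16.1 ± 1.79 to 0.564 ± 0.136 (log2 −4.99). Feature 2881 rose from 15.4 ± 5.37 to 53.7 ± 7.99 (log2 1.33). Feature 265 rose from 36.6 ± 6.57 to the ceiling of 100 on all 4 psah2k arrays, at least 2.73-fold on the deposited scale. These 4 passed under all 4 scalings. Whether any of them belongs to a disrupted gene was not tested.

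Arrays of numbers 1 and 2, and of 3 and 4, resembled each other more closely within each genotype. With the pairs averaged first, as an alternative chosen after seeing the data, 689 features were called, 346 higher and 343 lower. Separately, numbers 1 and 2 gave 933 calls and numbers 3 and 4 gave 820. Among the 1806 features tested in both, 871 were called with numbers 1 and 2 and 680 with numbers 3 and 4. Of these, 504 were called in the same direction and 1 in opposite directions, where independent lists would share 166. Both comparisons hold the same shift in intensity between the genotypes, so this agreement says nothing about its cause.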

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

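The tests of an offset, a scale factor, a loss of transcripts, array position, noise, shared arrays or RNA and splits of averaged pairs were chosen only after the result was seen, and the splits of the 8 samples were planned before.

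Features listed at 0 in all samples of a single genotype were left out of the test. Whatever the other genotype showed, 390 features were at 0 on all 4 WT arrays and 265 on all 4 psah2k arrays. Of these, 134 were at 0 on all 8 arrays. The balance reversed when every array of the other genotype had to be above 0. There were 98 features above 0 on all 4 WT arrays and at 0 on all 4 psah2k arrays, 15 of them with 1 gene. Their median WT intensity was 0.230 and the highest 1.46. Examples chosen after their values were seen are AT3G11150 with 0.726 ± 0.102, AT3G52550 with 0.543 ± 0.0383 and AT1G44830 with 0.441 ± 0.145 (SD, n = 4). In the other direction 9 features, none with 1 gene, were above 0 on all psah2k arrays and at 0 on all WT arrays, with a highest psah2k intensity of 0.150.

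After quantile normalization PSBW on psah2k 4 stood apart from the other psah2k arrays, at a log2 value of 5.48 against a median of 4.84 in the others. As deposited it did not, its 38.9 lying within the 34.4 to 45.2 of the other psah2k arrays. The normalized gap was 0.856 of the group's range, above the critical value of Dixon's test. Chance gives such a gap in about 5% of groups, and 1 of 77 groups tested showed one.

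The first pattern is the drop of dim and middling features on psah2k arrays, 87.3% of tested features having a lower deposited intensity there. One scale factor per array would shift bright and dim features alike, but the deposited log2 ratios of the 236 brightest features had a median above that of the rest by 2.16 log2 units (95% bootstrap interval 2.02 to 2.39). A subtracted constant stays open as part of the cause: over groups 5 to 9 of 10 by brightness the median intensity in WT exceeded that in psah2k by 0.318 to 0.391, a ratio of 1.23. The difference was smaller in groups 1 to 4, at 0.0869, 0.175, 0.191 and 0.275, with psah2k medians above 0, and it was −0.220 in the brightest group, which a constant alone would not give. Such a constant, a biological loss of many transcripts and a difference in labelling, hybridisation or background treatment between the genotypes cannot be told apart, because no feature of known amount is identified and each genotype has its own arrays.

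The second pattern is the set of 368 features lower under all 4 scalings. They did not crowd in any of 12 equal blocks of identifiers, the highest share being 1.28 times the overall share (permutation p of the chi-square over blocks = 0.216). This argues against a fault confined to 1 block, if identifiers follow position, which is not known. Shares were 19.2%, 20.0% and 19.0% in the adjacent blocks 8, 9 and 10, down to 11.6% in block 4, against 15.6% overall. Neighbouring blocks were not tested together. Noise near the floor stays open for part of them, since their median WT intensity of 0.635 lay between the median (0.437) and the upper quartile (0.819) of all tested features. For 111 of them the WT intensity was above that upper quartile. A transcript response to the genotype is a hypothesis that remains open beside a difference in hybridisation.

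The third pattern is the likeness of numbers 1 and 2, and of 3 and 4. In both genotypes the lowest rho within these pairs exceeded the highest across them, by at least 0.0154. The correlations were 0.981 to 0.987 within against 0.960 to 0.966 across in WT, and 0.881 to 0.897 against 0.853 to 0.866 in psah2k. A shared array or shared RNA stays open, since these correlations prompted the pattern and so cannot test it. No biological explanation was tested.

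Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 1246 called features, and the highest count of the others was 0. This excludes a chance split only if the 4 samples of a genotype are independent. With numbers 1-2 and 3-4 averaged as units there are only 3 splits, too few for a share under 0.05, and the real one gave 689 against at most 0. For the gene lists the count was 0 in the real split and at most 0 in the others, so 35 of 35 splits gave as many, which a real count of 0 fixes in advance and which says nothing about chance.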

How the results depend on the processing

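Settings on numbers 1-2 and 3-4 were chosen after seeing the data. As deposited 1890 features were called, with 172 higher and 1718 lower, and after median centring 396 were lower. With values of 0 set to each array's smallest positive value 415 were lower, and at an adjusted p under 0.01 830 features were called. Averaging numbers 1-2 and 3-4 gave 689 (346 higher, 343 lower), and numbers 3 and 4 alone 820, with 364 lower. In both, fewer samples entered the fit. The fry test called 1 gene list against 0. The other counts stayed within 1.5 times, with 1025 to 1082 when each array was left out and 1029 with a random block for numbers 1-2 and 3-4.

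As deposited, 6 named genes reversed: AT4G17260 (−0.46), CHLM (−1.72), FATB (−1.04), NTRC (−0.65), AT3G54210 (−0.30) and AT4G01310 (−1.09). PSBW reversed to 1.77 after median and 1.06 after upper quartile centring, and PSB27 to 1.21 and 0.51. CHLM was at −0.49 after upper quartile centring. With only numbers 1 and 2 CHLM was at −0.0454 and LHB1B2 at −0.25, and with only numbers 3 and 4 PSB27 and the photosystem II list median were at 0.26. LHB1B2, near 0 in the main setting, was at −0.0240 with array weights and between −0.0430 and 0.13 with each array left out. The list medians turned to 1.77 and 1.06 (photosystem II, median and upper quartile centring), −0.65 (redox) and −1.09 (ribosomal), both as deposited. The turns between scalings go with the shift of all tested features, whose median was −0.12 after quantile normalization and −1.77 as deposited. Median and upper quartile centring add about the same amount to every deposited log2 fold change. The cause of the shift itself stays open, and that of the turns in subsets of arrays was not tested. Among all 820 values of named genes under alternatives, 733 kept direction and side of the threshold, 62 lost the call in the same direction, 5 gained it and 20 turned direction. Setting values of 0 to the smallest positive value ended the call of 10 of the 38 named genes: AT2G39000, AT4G24160, AT4G17260, AT4G35660, AT1G01080, AT2G32040, AT5G17840, FATB, PSBW and AT3G52960.

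With the replicate number as a block, 1087 features were called, 558 higher and 529 lower, and AT4G24160 (adjusted p = 0.0686) and AT3G52960 were not among them. Deviations of samples with the same number correlated at 0.05, 0.12, 0.07 and 0.07, not all above 0.1. Each sample correlated best with its own number, the highest correlation with another number being 0.0116. This is a hint of a pairing from the data and not the design, so whether they share more than a number stays open. The main fit used no pairing. The targeted genes gave no value under any setting. Dim signals limit what can be read from the 12 largest rises, whose WT intensities were at most 0.207. They also limit the sizes of the 12 largest falls, whose psah2k means were at most 0.185.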

Other observations

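The tests and genes in this part were all chosen after the data were seen. Further features in the fixed lists each match several genes of a family and name none of them. A feature shared by LHCB4.1, LHCB4.2 and LHCB4.3, minor antenna proteins of photosystem II, had a log2 fold change of 1.41 (limma adjusted p = 0.00155) and 0.12 as deposited, where it did not pass. A feature shared by ATPC1 and ATPC2, gamma subunits of the plastid ATP synthase, rose by 1.12 and had 0.24 as deposited, without passing. A feature of HEME1 and HEME2, of tetrapyrrole synthesis, had 1.51, and −0.21 as deposited. Of 2 features of the ascorbate peroxidases TAPX and SAPX, one had 2.96 and the other 0.31 (adjusted p = 0.187), against 0.13 and −1.18 as deposited, where the second passed as lower.

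Some plastid genes outside the lists are given as values only. Cpn60beta4, a subunit of the plastid chaperonin, fell under all 4 scalings (log2 −0.71, adjusted p = 0.0285), from 0.335 ± 0.0398 to 0.0364 ± 0.0295 (SD, n = 4). PPDK, the pyruvate, phosphate dikinase gene, fell in 3 scalings (log2 −0.55), and HEMA3, a glutamyl-tRNA reductase gene, in 3 (log2 −0.92), but HEMA3 was at 0.11 after median centring. NdhS, a subunit of the plastid NDH complex, had mean intensities of 6.03 and 7.01, and its log2 fold change of −0.21 did not pass (adjusted p = 0.202), though it passed as higher after median and upper quartile centring (2.13 and 1.42). SRX, the sulfiredoxin gene, passed as higher after quantile normalization (log2 1.38, adjusted p = 0.00474), as did LPA19, of photosystem II assembly (0.83, adjusted p = 0.00658), FZL, a thylakoid dynamin-like protein gene (2.09, adjusted p = 0.0298), and THIC, of thiamine synthesis (0.87). As deposited they were at −0.67, −1.35, −0.44 and −0.50, and LPA19 passed there as lower. The other 7 of these 15 genes, PIFI, CCB3, SECE1, CCS, OTP70, CRR21 and Cpn60beta3, did not pass after quantile normalization, Cpn60beta3 having log2 −0.50 (adjusted p = 0.292). As deposited all of them but CCB3 passed as lower. PIFI, at 0.92 after median centring, was also called higher under 1 of the 4 scalings.

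A hypothesis was that photosynthesis genes rose together relative to other features of like brightness. The 8 tested members of the photosystem, antenna, Calvin cycle and chlorophyll synthesis lists had a median log2 fold change of 0.32, at percentile 89.2 of 10000 random lists matched on mean log2 value. The central 95% of those lists ran from −0.76 to 0.55. With so few features the test does not decide it.

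Some listed genes had too few values for the test. The SBPASE feature, of the Calvin cycle, was listed at 0 on all 4 WT arrays and above 0 on 3 psah2k arrays. The AT3G13120 feature (RPS10) was above 0 on all 4 WT arrays and on 1 psah2k array.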
